A study of Sus scrofa with 6 samples.

How the data were processed

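Total RNA was isolated with TRIzol from cultured immature Sertoli cells of fetal pig testis, 3 control and 3 treated with 250 µM AA2P, and sequenced on a HiSeq X-Ten in a single lane, per the labels' protocols. The cells were grown in minimum essential medium with 10% serum and 1% antibiotic at 37 °C in 5% CO2, per the labels' protocols. The submitters' processing notes name bcl2fastq, which turns sequencer output into reads, and HISAT2 2.0.5, a spliced aligner. The tool that counted reads, its strand setting, the annotation and the genome build were not given in the sources used here. The authors deposited whole-number counts of reads per gene, which are not normalized, and every later value was computed from these counts. Because the counting tool is unknown, genes with near-identical copies or pseudogenes and genes that overlap another, on either strand, are uncertain. No coordinates are printed, since the build is unknown.

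The table held 17670 pig Ensembl gene identifiers, none of them at 0 in all 6 libraries, and genes without a row were not analysed here. A symbol was found for 13141 of them in a table of gene names, and 10814 of the tested genes had one. Library totals ran from 18747307 to 23521291 counts. A level of 3 counts, the most that a count of 0 allows, corresponds to 0.123 to 0.165 CPM, and this covers counting error only.

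Differential expression was tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test, with TMM factors, the filterByExpr filter given the group, a model with the group alone, and Benjamini-Hochberg adjustment over the 12701 genes tested. The threshold was an adjusted p of 0.05. TMM factors were 0.944, 0.941 and 0.945 in the control libraries and 1.07, 1.06 and 1.05 in the AA2P libraries, and the common biological coefficient of variation was 5.49%. Log2 fold changes are AA2P over control, and standard errors were taken as the absolute log2 fold change over the square root of the F statistic. CPM values are TMM scaled.

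Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists with at least 5 tested members. Camera asks whether a list moved more than the other genes did. The 32 lists covered Sertoli cells, blood-testis barrier junctions, glycolysis, HIF targets, collagens, collagen processing, basement membrane and adhesion matrix, matrix proteases, integrins, TGF-beta and BMP response, S phase, G2 and M phase, TET and lysine demethylases, ascorbate transport, NRF2 and antioxidant genes, the unfolded protein response, heat shock proteins, cholesterol, interferon-stimulated genes, inflammatory cytokines, p53 targets, iron, immediate early genes, retinoids, Leydig, smooth muscle, stromal, endothelial, macrophage and germ cell markers, mitochondrial genes and ribosomal proteins. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

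The rule named genes with a symbol in 4 parts. The first took the 10 called genes with the largest increase and the 10 with the largest decrease among those with a mean of at least 5 CPM and no overlap between the groups. The others took the 5 smallest p-values, up to 4 called members of each list by smallest p, and the ascorbate transporters SLC23A1 and SLC23A2. VEGFA, AMH, ALDOA, INHA, DHH, NR5A1, AMHR2, HSPD1, HSPE1, ACTA2, PDGFRB, CYP17A1 and CSF1R lie outside this rule and were chosen after seeing their values. The same holds for the cilium and tubule genes named in the closing section.

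The procedure was tested on simulated counts for the AA2P against control comparison. They were drawn for the 12701 tested genes from the means, dispersions and library sizes of these libraries, and 12600 genes passed the filter. Far fewer genes were changed in the simulation than were called in the data, so recovery and false share may differ there. It recovered 36 of 50 genes changed by 0.5 on the log2 scale, 47 of 50 at 1, 50 of 50 at 2 and 49 of 49 at 3. Of its 199 calls, 17 were false, a share of 8.54%.

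The alternatives were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, an estimated correlation in camera, and the rotation test fry. Scaling by library totals, the called members of each list without AA2P replicate 3, and 3 lists without their shared members were added after seeing the data. No sample was left out of the comparison. Some genes that the rule names are not reported here.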

Results

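The series measured gene expression by RNA sequencing in immature Sertoli cells, the somatic nurse cells of the seminiferous tubule, taken from the testes of pigs at 80 to 90 days of gestation. The comparison asked how the transcriptome of these cells in culture differed after treatment with L-ascorbic acid 2-phosphate (AA2P), a stable form of vitamin C. AA2P was given at 250 µM after 6 h of culture, and the length of the treatment was not given in the sources used here. There were 6 libraries, 3 from control cells and 3 from AA2P cells. The deposited read counts summed to 23521291, 19299585 and 21818299 in control libraries 1 to 3 and to 18747307, 19005552 and 23122000 in AA2P libraries 1 to 3. The table held 17670 genes, of which 12701 had enough counts to be tested. Nothing in the labels said that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

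The cells with AA2P differed from control cells in genes of many kinds. ANPEP, PDZK1 and CLDN2, which encode a brush border peptidase, a scaffold of transporters and a claudin, and the genes of cholesterol synthesis were higher with AA2P. Glycolytic enzymes, hypoxia-inducible factor (HIF) targets, collagen-modifying enzymes, fibronectin, inflammatory cytokines and genes of the unfolded protein response were lower. These are calls of the set test camera at its preset correlation, apart from the single genes, and the HIF list had adjusted p = 0.154 and each other list, cholesterol included, adjusted p = 0.303 with an estimated correlation. Fibronectin (FN1), a large matrix glycoprotein, was among the most abundant transcripts and fell 3.43-fold, from 26042 ± 825 to 7602 ± 990 CPM (read counts scaled to a fixed library size; SD, n = 3). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6615 of the 12701 genes passed an adjusted p of 0.05, 3302 of them higher and 3313 lower with AA2P. A change of at least 2-fold was seen in 1144 called genes, of which 702 were higher and 442 lower. In 59.3% of the tested genes the 3 control and 3 AA2P libraries did not overlap, where chance gives 10%.

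The split between higher and lower genes depended on the scaling of the libraries. With library totals in place of TMM factors, 5727 genes were called higher and 1822 lower, and the median log2 fold change of all tested genes moved by 0.17. The 10 most abundant genes took 10.6% to 11.1% of the counts in the control libraries and 7.30% to 7.68% in the AA2P libraries, and FN1 alone took 2.41% to 2.54% and 0.722% to 0.916%. Changes below are relative to the TMM scaling.

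The libraries separated by group along the first principal component, which held 84.4% of the variance. Pearson correlations of log2 CPM across genes, which are not independent replicates, ran from 0.993 to 0.995 within groups and from 0.956 to 0.973 between groups. AA2P library 3 lay nearer the controls than the other AA2P libraries, with a mean correlation to the control libraries of 0.970 against 0.959 for library 1 and 0.961 for library 2. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom of 2.70 to 12.1, so no library was counted as a copy of another.

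**Figure D1:**
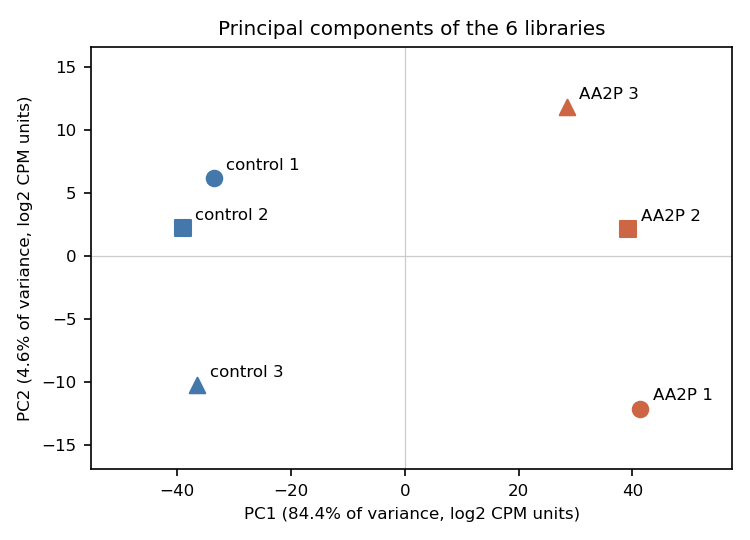
Each point is a library, placed by its first (horizontal) and second (vertical) principal component scores of log2 CPM over the tested genes, with control in blue and AA2P in orange. The control libraries lie between -39.0 and -33.6 on the first component and the AA2P libraries between 28.4 and 41.4, with AA2P library 3 nearest the controls.

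The 10 largest increases included genes whose products sit in apical membranes. GDPD2, a glycerophosphodiester phosphodiesterase family member, rose 26.8-fold from 1.31 ± 0.132 to 35.5 ± 8.75 CPM (SD, n = 3). PKHD1, which encodes the ciliary protein fibrocystin, rose 25.1-fold to 186.6 ± 44.7 CPM, and CLDN2, a claudin of leaky epithelia, rose 21.6-fold to 25.4 ± 4.49 CPM. ANPEP, the brush border aminopeptidase N, rose from 18.1 ± 3.90 to 263 ± 42.9 CPM, with a log2 fold change of 3.85 and a standard error of 0.13. PDZK1, a scaffold of apical transporters, KCNJ16, a potassium channel, and ANKS4B, a microvillus protein, rose 13.9-fold, 12.4-fold and 10.4-fold. PROC, which encodes protein C, and C11orf86 rose 12.0-fold and 11.7-fold. Adjusted p-values of the genes named here lay between 2.2e-12 (ANPEP) and 3.4e-09 (PDZK1) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

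The largest decreases included a phosphate transporter, calgranulins and a fructose transporter. SLC34A2, a sodium-phosphate cotransporter, fell from 11.3 ± 1.31 to 0.200 ± 0.230 CPM (SD, n = 3), and PADI1, a peptidylarginine deiminase, fell 47.5-fold to 0.294 ± 0.242 CPM. Both were near the level of 3 counts in AA2P libraries, and SLC34A2 had none in library 1, so their fold changes rest on few counts. Without AA2P replicate 3 the log2 fold changes of SLC34A2, PADI1, S100A8 and ARG1 were -7.12, -6.37, -5.27 and -4.33, against -5.67, -5.57, -4.66 and -3.73 with it. MMRN2 fell 27.2-fold and CYRIA 22.7-fold. S100A8 and S100A12, calcium-binding proteins of inflammation, fell 25.3-fold and 16.9-fold, and ARG1, an arginase, fell 13.2-fold. The adhesion receptor ADGRA2 and the cytokine IL11 fell 9.06-fold and 8.88-fold. SLC2A5, the fructose transporter GLUT5, fell from 96.7 ± 6.84 to 7.91 ± 0.594 CPM and had the smallest adjusted p of all genes, 3.6e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among genes with a symbol, the next smallest p-values belonged to CCN3, P4HA1, tissue factor (F3) and PPP1R3C. CCN3, a matricellular protein, fell from 5359 ± 36.5 to 1263 ± 45.5 CPM. F3 fell 3.81-fold, and PPP1R3C, a glycogen-targeting subunit of protein phosphatase, fell 4.27-fold.

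**Figure D2:**
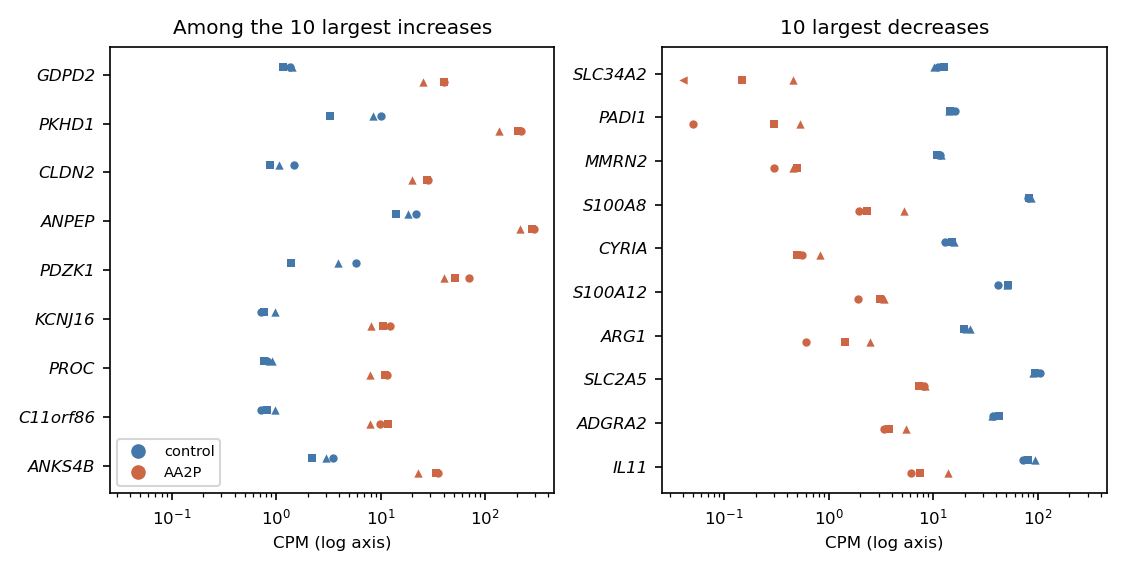
Each point is the CPM of a gene in a library on a log axis, for genes among the 10 largest increases (left) and for the 10 largest decreases (right), with control in blue, AA2P in orange, and circles, squares and triangles for replicates 1, 2 and 3; a left-pointing triangle marks a library with 0 counts. Only genes whose control and AA2P libraries do not overlap could be chosen, so none drawn overlaps, as in GDPD2 with means of 1.31 and 35.5 CPM.

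Of 32 gene lists fixed before the data were examined, 30 had enough tested members for a set test, and 15 passed camera's adjusted p of 0.05, 5 higher and 10 lower with AA2P. None of the 15 calls held when camera estimated the correlation between genes from these 6 libraries, where 2 lists had an unadjusted p under 0.05, while fry called 27 lists.

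Glycolysis, HIF target and collagen processing genes fell together. Of 18 tested genes of glycolysis and lactate export, 16 fell and 1 rose, and the median log2 fold change was -0.85. Lactate dehydrogenase A (LDHA) fell from 2008 ± 56.8 to 657 ± 26.1 CPM (SD, n = 3), and PGK1, TPI1 and ENO1 fell 2.30-fold, 2.52-fold and 2.66-fold. Of 27 HIF targets, 23 fell and none rose, with a median of -0.80. The collagen prolyl hydroxylase subunits P4HA1 and P4HA2 fell 3.82-fold and 2.56-fold, the lysyl hydroxylase PLOD2 2.18-fold and the stress gene NDRG1 2.20-fold. VEGFA, a HIF target that codes for a growth factor of blood vessels, was at 93.4 ± 2.38 CPM in controls and 94.3 ± 4.12 with AA2P. Among 23 collagen processing genes 19 fell and none rose, with a median of -0.69, and the prolyl 3-hydroxylase P3H2 fell from 610.3 ± 13.2 to 270.5 ± 19.3 CPM. Camera with Benjamini-Hochberg adjustment gave the glycolysis, HIF target and collagen processing lists adjusted p-values of 9.5e-08, 6.6e-10 and 4.4e-08. In the same order the lists had adjusted p = 0.303, 0.154 and 0.303 with an estimated correlation. Counts adjusted over the list alone were 1 higher and 16 lower, 0 and 23, and 0 and 19. With library totals they were 2 and 15, 1 and 21, and 1 and 19 over all genes. The lists share members such as P4HA1, P4HA2 and PLOD2. Without the shared members, 16 of 20 HIF targets fell with a median of -0.67, 13 of 15 glycolysis genes with a median of -0.87 and 15 of 19 collagen processing genes with a median of -0.56.

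Genes of the extracellular matrix and of adhesion to it fell. In the basement membrane and adhesion matrix list 13 of 21 genes fell and none rose, including FN1, the laminin chain LAMA4, which fell 3.10-fold, and tenascin C (TNC), which fell 6.77-fold. With library totals 10 genes of that list fell and 4 rose, with a median of -0.20 against -0.37. THBS1, a matricellular protein, fell from 8867 ± 379 to 5661 ± 106 CPM (SD, n = 3). In the matrix protease list 12 of 18 genes fell and 3 rose. MMP7 fell 6.00-fold and TIMP3 1.71-fold, while the protease inhibitor TIMP4 rose 3.86-fold and the protease ADAMTS9 rose 1.73-fold. In the integrin and focal adhesion list 17 of 22 genes fell and 2 rose. ITGA6, ITGB1 and CD44 fell 2.46-fold, 1.82-fold and 2.17-fold, and the collagen receptor chain ITGA1 rose from 127 ± 2.79 to 511 ± 91.0 CPM. Of 19 TGF-beta and BMP response genes 11 fell and 5 rose, and CCN2, TGFBI, TGFB1 and SMAD7 fell 2.90-fold, 3.40-fold, 1.63-fold and 1.62-fold. Camera's adjusted p-values for these lists, Benjamini-Hochberg adjusted, were 0.000618, 0.0103, 3.6e-05 and 0.0471, and each had adjusted p = 0.303 with an estimated correlation. Adjusted over the list alone, 0, 3, 3 and 5 genes were higher and 13, 12, 18 and 11 lower. The TGF-beta list missed the threshold without control replicate 1, at an adjusted p of 0.0665. Its adjusted p lay between 0.00615 and 0.0665 over 11 alternatives. Such ranges, here and below, leave out the estimated correlation and fry.

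The collagens went both ways and their list did not pass the set test. Of 19 tested collagen genes 11 fell and 5 rose, the same as adjusted over the list alone, with a camera adjusted p of 0.0505. At the preset correlation the list did pass under 6 of the planned camera alternatives and with library totals, its adjusted p lying between 0.00234 and 0.0794 over 11 alternatives. With an estimated correlation camera gave it an adjusted p of 0.396. COL15A1 fell 8.03-fold, COL6A1 1.88-fold and COL3A1 2.10-fold, while the basement membrane chain COL4A5 rose 2.45-fold from 12.8 ± 1.31 CPM (SD, n = 3).

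Cholesterol genes rose as a group. All 21 tested genes of cholesterol synthesis and uptake were higher with AA2P, the same adjusted over the list alone, and their median log2 fold change was 1.20. INSIG1, a sterol-regulated anchor protein, rose from 36.2 ± 1.70 to 126 ± 16.3 CPM (SD, n = 3). Squalene epoxidase (SQLE) and squalene synthase (FDFT1) rose 3.05-fold and 2.60-fold. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 4.5e-10, against adjusted p = 0.303 with an estimated correlation.

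Genes of the unfolded protein response fell and heat shock genes rose. Of 24 unfolded protein response and ATF4 target genes 23 fell and none rose, also adjusted over the list alone, with a median of -0.61. Asparagine synthetase (ASNS) fell from 722 ± 14.8 to 198 ± 34.9 CPM (SD, n = 3), and TRIB3, PSAT1 and EDEM1 fell 4.97-fold, 2.34-fold and 1.76-fold. Of 16 genes of the heat shock list 10 rose and 1 fell, or 11 and 1 adjusted over the list alone, with a median of 0.26. With library totals 12 rose and 0 fell, with a median of 0.43. The 10 that rose include HSPD1 and HSPE1, which encode mitochondrial chaperonins, while the others named here act in the cytosol. The chaperones HSPH1, HSPA8, HSP90AA1 and DNAJA1 rose 1.96-fold, 1.71-fold, 1.56-fold and 1.32-fold, and the reads of HSPA8 and HSP90AA1 could be shared with near-identical copies. Camera's adjusted p-values were 7.1e-10 and 0.00444 after Benjamini-Hochberg adjustment, and both lists had adjusted p = 0.303 with an estimated correlation.

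Inflammatory genes fell and interferon-stimulated genes rose. Of 15 tested cytokine, chemokine and related genes 13 fell and none rose, also adjusted over the list alone, with a median of -1.31. Complement C3 fell from 9640 ± 214 to 2667 ± 654 CPM (SD, n = 3), IL6 fell 2.18-fold, and TNFAIP3, an inhibitor of NF-kappaB signalling, fell 2.63-fold. Of 17 interferon-stimulated genes 10 rose and 1 fell, the same adjusted over the list alone, with a median of 0.40. OAS2, IFIT1, IFIT2 and MX2, which belong to families with similar copies, rose 1.66-fold, 2.12-fold, 2.78-fold and 1.49-fold. Camera's adjusted p-values were 4.6e-06 for the inflammatory and 0.0257 for the interferon list after Benjamini-Hochberg adjustment, and both had adjusted p = 0.303 with an estimated correlation. With library totals the interferon list had an adjusted p of 0.0574, in a range of 0.00662 to 0.0574 over 11 alternatives.

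Immediate early and p53 target genes went both ways. Of 18 immediate early genes 9 fell and 5 rose, or 10 and 5 adjusted over the list alone, with a camera adjusted p of 0.108, or 0.0136 with library totals in a range of 0.0136 to 0.134 over 11 alternatives. ATF3, IER3, FOSL2 and KLF4 fell 1.82-fold, 2.28-fold, 1.94-fold and 1.97-fold. Of 17 p53 target and apoptosis genes 7 rose and 5 fell, also adjusted over the list alone. PMAIP1 fell 3.93-fold and BIRC3 1.58-fold, and BCL2L1 rose 1.51-fold. The median of that list was 0.09 and its mean -0.09, and camera gave an adjusted p of 0.929. With library totals 10 rose and 5 fell, with a median of 0.26.

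Cell cycle genes rose by small amounts. Of 20 S phase genes 13 rose and 2 fell, with a median of 0.25, and of 21 G2 and M phase genes 12 rose and none fell, with a median of 0.20. Both counts were the same adjusted over the list alone. With library totals 17 and 20 genes were called higher and 0 lower, with medians of 0.42 and 0.37. CCNE2 rose from 7.30 ± 0.146 to 14.5 ± 1.92 CPM (SD, n = 3), and CDC6, MCM4 and TK1 rose 1.72-fold, 1.30-fold and 1.48-fold. The mitotic genes KIF11, BIRC5, KIF20A and TTK rose 1.29-fold, 1.28-fold, 1.23-fold and 1.26-fold. Camera's adjusted p-values were 0.00505 and 0.00471 after Benjamini-Hochberg adjustment, and both lists had adjusted p = 0.396 with an estimated correlation.

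Ribosomal protein genes fell slightly, but with library totals 2 fell and 1 rose, with a median of -0.03. Of 19 tested genes 15 fell and none rose, also adjusted over the list alone, with a median of -0.20 and a camera adjusted p of 0.00190 after Benjamini-Hochberg adjustment, against adjusted p = 0.379 with an estimated correlation. RPL4, RPL14 and RPL10, genes with many pseudogenes, fell 1.25-fold, 1.22-fold and 1.20-fold, but with library totals RPL10 missed the threshold. Of 12 mitochondrially encoded genes 7 fell and 1 rose, the same adjusted over the list alone, with a camera adjusted p of 0.0505. With library totals 4 fell and 2 rose, and over 11 alternatives the adjusted p lay between 0.0270 and 0.0936, passing in 5 planned ones. Camera with an estimated correlation gave the mitochondrial list an adjusted p of 0.439. CYTB, COX2, ATP6 and ND4L fell 1.66-fold, 1.59-fold, 1.30-fold and 1.35-fold.

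The ascorbate transporters moved apart. SLC23A1, an epithelial sodium-ascorbate cotransporter, rose 3.71-fold from 2.56 ± 0.417 to 9.51 ± 0.820 CPM (SD, n = 3), while SLC23A2, the widely expressed one, fell 1.68-fold from 143 ± 6.93 to 85.1 ± 6.13 CPM. Both passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values of 1.7e-08 and 2.2e-08. Of 10 genes of ascorbate transport and recycling 4 rose and 2 fell, also adjusted over the list alone, with a camera adjusted p of 0.128, and with library totals 7 rose and 1 fell. RGN rose 3.46-fold to 2.92 ± 0.428 CPM. The orphan family member SLC23A3 was at 0.0162 ± 0.0280 CPM in controls, under the level of 3 counts, and at 0.723 ± 0.159 CPM with AA2P.

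Of 21 TET and histone lysine demethylase genes, whose enzymes need iron and 2-oxoglutarate, 11 fell and 3 rose, also adjusted over the list alone. KDM3A, KDM4B, KDM6B and TET3 fell 1.64-fold, 1.51-fold, 1.54-fold and 1.40-fold. The list had a camera adjusted p of 0.0505, in a range of 0.0205 to 0.0879 over 11 alternatives, of which 3 passed. Its adjusted p was 0.303 by camera with an estimated correlation. With library totals 8 genes were called higher and 6 lower, with a median of -0.02. KDM3A and KDM4B were also in the HIF target list. Among 23 NRF2 and antioxidant genes 8 fell and 7 rose, or 9 and 7 adjusted over the list alone, with a camera adjusted p of 0.651. The cystine transporter SLC7A11 fell 5.56-fold and the malic enzyme ME1 1.49-fold, while the glutathione peroxidase GPX3 and the glutathione synthesis enzyme GCLC rose 1.76-fold and 1.47-fold. Among 16 iron genes 8 fell and 5 rose, also adjusted over the list alone, with a camera adjusted p of 0.227. Lipocalin 2 (LCN2) fell 8.10-fold, the transferrin receptor TFRC 1.59-fold, and the STEAP family members STEAP1 and STEAP2 1.80-fold and 1.55-fold. The medians of the NRF2 and iron lists, -0.10 and -0.09, turned to 0.07 and 0.08 with library totals, which called 10 higher and 7 lower in the first and 7 each way in the second.

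Sertoli cell genes went both ways, and some were close to 0 in every library. Of 10 tested genes of the Sertoli list 6 fell and 3 rose, also adjusted over the list alone, with a camera adjusted p of 0.122, or 0.0136 with library totals in a range of 0.0136 to 0.203 over 11 alternatives. Clusterin (CLU), a major secreted glycoprotein, fell from 4230 ± 168 to 1302 ± 266 CPM (SD, n = 3). The transcription factor SOX9 fell 5.20-fold from 11.6 ± 0.648 CPM and keratin 18 (KRT18) 1.71-fold. Anti-Müllerian hormone (AMH) was at 36.4 ± 1.52 CPM in controls and 34.5 ± 2.35 with AA2P. A further 7 genes of the list had too few counts to be tested. Among them INHA had 2, DHH 11, NR5A1 14 and AMHR2 52 counts over all 6 libraries. Another 8, namely SOX8, GATA4, FSHR, CLDN11, DMRT1, PTGDS, SHBG and NR0B1, had no row under these symbols and were not analysed here. The count table held no gene at 0 in all libraries, so a missing row can mean no counts or no matched symbol. A low count here does not show that a transcript was absent, since ALDOA, a glycolytic enzyme of most cells, had 12 counts over the same libraries.

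**Figure D3:**
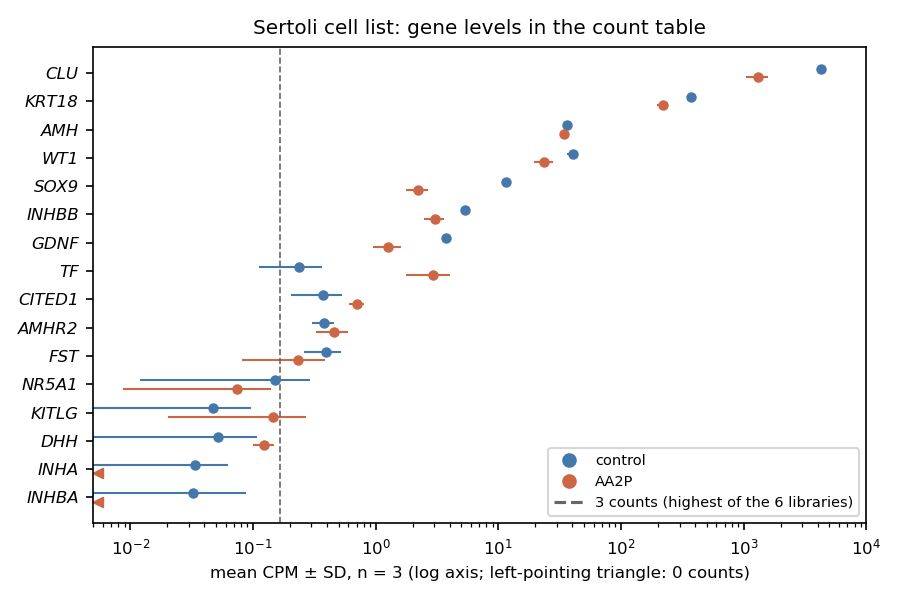
Mean CPM on a log axis of Sertoli list genes in the count table, control in blue and AA2P in orange, with bars of 1 SD (n = 3) that run to the left edge where they pass 0, left-pointing triangles for groups with 0 counts, and a dashed line at the CPM of 3 counts. CLU lies at 4230 and 1302 CPM and AMH at 36.4 and 34.5, while INHA and DHH lie below the line in both groups.

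Junction genes of the blood-testis barrier, which Sertoli cells form, also went both ways. Of 16 tested genes 9 fell and 3 rose, also adjusted over the list alone. The gap junction gene GJA1 fell 2.37-fold, the adhesion genes VCL and NECTIN3 fell 1.47-fold and 1.42-fold, and the tight junction scaffold TJP3 rose 2.29-fold. The list's median was -0.14, its mean 0.13 and its median with library totals 0.03, with 7 genes then called higher and 4 lower, and camera gave an adjusted p of 0.256. Of 13 genes of retinoid metabolism and response 8 fell and 4 rose, also adjusted over the list alone, with a camera adjusted p of 0.122, or 0.0180 with library totals in a range of 0.0180 to 0.209 over 11 alternatives, and library totals called 5 lower and 4 higher. TGM2, ALDH1A1, STRA6 and the retinoic acid hydroxylase CYP26B1 fell 4.53-fold, 1.76-fold, 1.76-fold and 5.06-fold.

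No list of markers of another testis cell type passed the set test, which asks about change with AA2P and not about presence. Too few counts for a test were found for ACTA2, PDGFRB, CYP17A1 and CSF1R, with 29, 2, 3 and 3 over all 6 libraries. Other members were far higher, such as CD74 at 507 CPM in controls. As with ALDOA, a low count does not show that a transcript was absent. Of 13 smooth muscle and peritubular myoid genes 6 fell and 2 rose, or 7 and 2 adjusted over the list alone. Desmin (DES) fell 4.64-fold, SMTN 1.55-fold and ACTG2 2.35-fold, and MYLK rose 1.30-fold. The list had a camera adjusted p of 0.227 and a median of -0.15 that was 0.02 with library totals, which called 4 genes each way. Of 5 stromal genes 3 rose and 2 fell, among them NR2F2 and NR2F1, which rose 2.02-fold and 1.91-fold, and GLI1, which fell 4.98-fold, with a camera adjusted p of 0.433. Of 5 endothelial genes PECAM1 rose 3.10-fold to 6.97 ± 0.875 CPM (SD, n = 3), FLT1 and EGFL7 fell 1.54-fold and 1.59-fold, and camera gave an adjusted p of 0.940. Of 8 macrophage and leukocyte genes 3 fell and 2 rose, with a camera adjusted p of 0.857, a median of -0.10, a mean of 0.04 and a median of 0.07 with library totals. AIF1 rose 7.09-fold to 5.17 ± 0.348 CPM, TYROBP fell 5.25-fold to 0.286 ± 0.110 CPM, CD14 fell 1.39-fold, and CD74 fell 1.16-fold but missed the threshold with library totals. The Leydig and germ cell lists had 4 and 3 tested genes and no set test. SCARB1 fell 1.95-fold and POR 1.16-fold, the latter call being lost without control replicate 1 or 2, without AA2P replicate 1 or 2 and with library totals, and the germ cell gene PIWIL2 fell 6.12-fold to 0.694 ± 0.175 CPM. Counts adjusted over the list alone were the same as over all genes for the stromal, endothelial, macrophage, Leydig and germ cell lists.

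**Figure D4:**
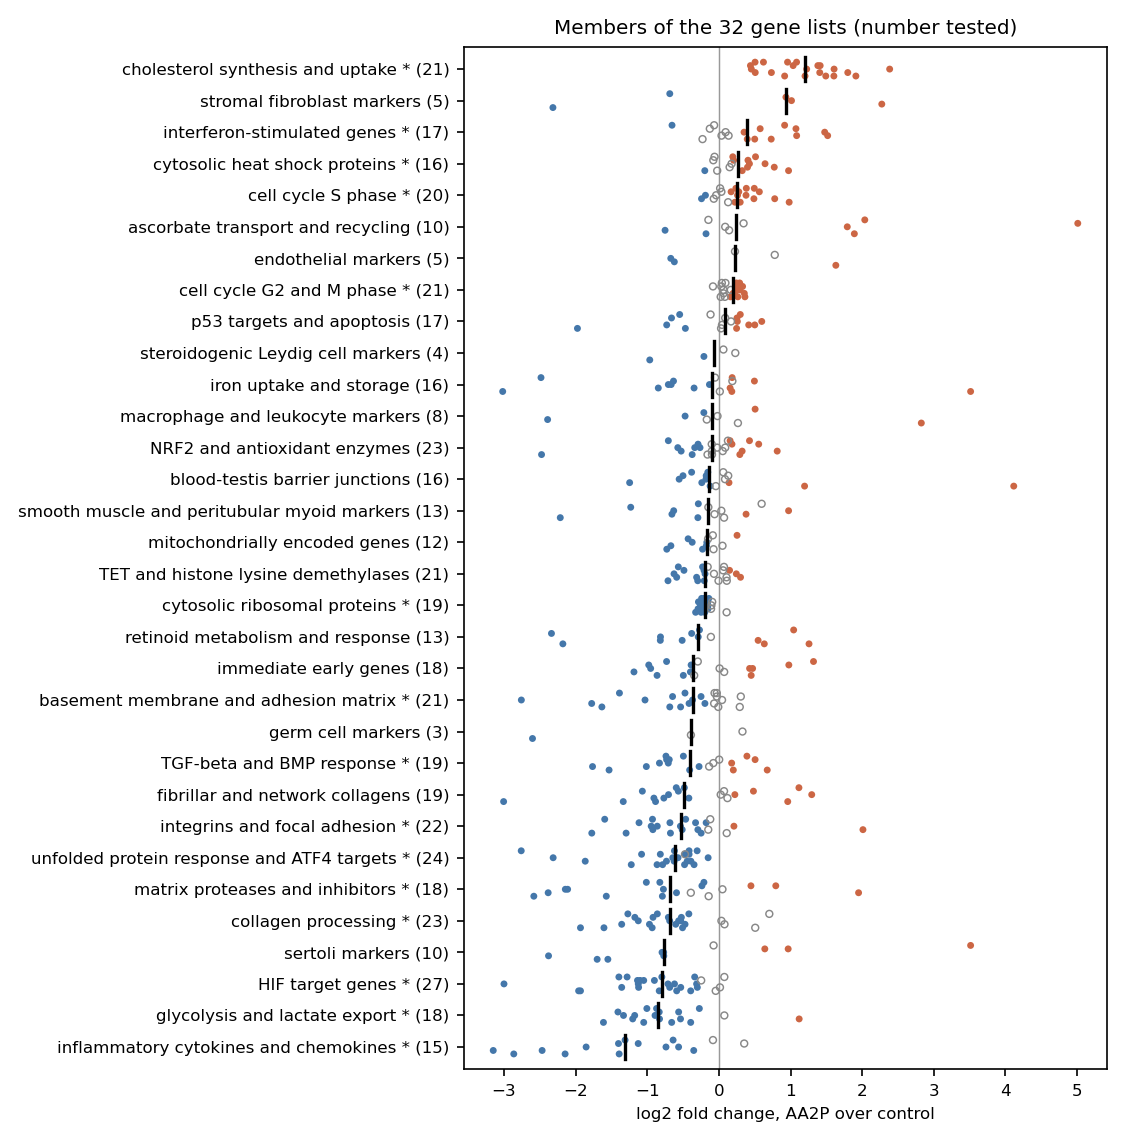
Each point is a tested member of a gene list at its log2 fold change of AA2P over control, orange or blue where called higher or lower and open grey where not called; black bars are list medians, numbers of tested genes are in parentheses, and stars mark lists past camera's adjusted p of 0.05. The medians run from -1.31 for inflammatory genes to 1.20 for cholesterol genes; with library totals those of the junction, NRF2, iron, smooth muscle, macrophage and Leydig lists turn positive.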

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

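The runs with library totals, without members shared between lists and of list members without AA2P replicate 3 were chosen after the result was seen, and the other alternatives before the data were examined. Of the alternatives, only library totals moved a count of called genes by over 1.5 times. With them 5727 genes were called higher and 1822 lower, against 3302 and 3313 with TMM factors, and 75.9% of calls were higher. The median of all genes moved by 0.17 on the log2 scale. This follows from dropping the TMM factors, 0.941 to 0.945 in control and 1.05 to 1.07 in AA2P libraries. Why the factors differed between the groups was not tested. Under the other scalings, filters and tests, between 6048 (DESeq2 Wald test) and 6925 genes (no low count filter) were called. Leaving out 1 library gave 5715 to 6875 calls, 2869 to 3438 of them higher and 2845 to 3437 lower, with 1151 to 1312 of at least 2-fold. An adjusted p of 0.01 kept 2547 higher and 2548 lower. No gene called both in the reported fit and in an alternative changed sign.

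Of 30 lists, 15 passed camera with its preset correlation, 0 with an estimated correlation and 27 by fry, which asks whether a list moves one way rather than whether it moves more than other genes; with 6 libraries the estimated correlation is imprecise, and the cause was not tested. Between 14 and 18 lists passed under the other alternatives. Of 141 named genes, 4 lost their call with library totals, among them POR, CD74 and RPL10, and POR alone did so when a library was left out.

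No pairing of the samples by replicate number was seen, though 3 libraries per group are too few to exclude one. Deviations from the group means of same-numbered libraries correlated at -0.04, -0.02 and -0.06, and those of unlike numbers at -0.07 to 0.11. With the replicate block 3094 genes were called higher, 3110 lower, 1146 by at least 2-fold, and 16 lists passed. Depth limits genes near 3 counts. In simulation 36 of 50 changes of 0.5 on the log2 scale were found, with far fewer genes changed than were called here.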

Other observations

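Chosen only after the result was seen were the tests on the tubule transcription factors and on the depth of AA2P library 3, and the condition added to the mixing test named below. The themes of the cilium and tubule lists were also picked after genes of both kinds had been seen to rise. Genes of motile cilia rose with AA2P in a list outside the 32 fixed ones. Some cilium genes had been noticed first, so the list held only genes whose values had not been looked at. The theme still came from a rise seen in these same 6 libraries, so the test is not independent support. Some members, such as GMNC at 0.0300 CPM in controls and 0.897 CPM with AA2P, passed the low count filter through the AA2P libraries alone. Such genes could only rise. Of 37 tested, 36 rose, 0 fell and 1 was not called, with a median log2 fold change of 1.00. The axonemal dynein heavy chains DNAH6, DNAH12 and DNAH7 rose from 89.2 to 179 CPM, from 42.9 to 118 CPM and from 6.36 to 25.1 CPM (means, n = 3). DNAI3 rose from 20.9 to 54.1 CPM and ZMYND10, a dynein assembly factor, from 28.4 to 67.7 CPM. Camera with Benjamini-Hochberg adjustment over this and the next list gave an adjusted p of 6.9e-16, and adjusted p = 0.0427 with an estimated correlation.

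Genes of the renal proximal tubule rose as well. In a list chosen in the same way, 22 of 28 tested genes rose, 4 fell and 2 were not called, with a median of 1.09. ABCC2, an apical export pump, rose from 393 to 715 CPM, NHERF1, an apical scaffold, from 58.9 to 145 CPM and SLC17A1, a phosphate transporter, from 7.53 to 26.3 CPM. Camera gave an adjusted p of 1.9e-06 with Benjamini-Hochberg adjustment, and adjusted p = 0.0427 with an estimated correlation. These values were adjusted over this and the cilium list only, while those of the fixed lists were adjusted over 30. They cannot be set side by side, since camera with an estimated correlation gave the HIF target list an unadjusted p of 0.00513. The limits named for the cilium list hold here too. The 4 that fell were ARG2, SLC1A1, SLC4A4 and SLC26A6. With library totals the medians of the tubule and cilium lists were 1.26 and 1.17, and without AA2P replicate 3 they were 1.11 and 1.05. Neither list shares a gene with the 32 fixed lists. In every library 24 of the 28 tubule and 33 of the 37 cilium genes had more than 3 counts. The cells labelled Sertoli thus expressed most tested genes of both lists without AA2P too.

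A first pattern is this tubule expression in cells labelled Sertoli, where transcription factors of the renal tubule were present in control cells, with PAX2 at 98.7 and HNF4A at 38.6 CPM, while INHA had 2 counts in all. A larger share of tubule cells in the AA2P libraries would raise these factors alike if no other cells expressed them. Their log2 fold changes ran from -0.70 for EMX2 and 0.44 for PAX2 to 2.62 for SIM1, a span of 36.9 standard errors, but expression in other cells was not measured, so a larger share stays open. A wider rise of both gene programmes within the cells is consistent with the medians of 1.09 and 1.00 and remains a hypothesis beside it. Whether the cultures held Sertoli cells that had changed in culture, cells of the neighbouring mesonephros or other cells may not be settled here, since AMH stood at 36.4 CPM and genes such as ALDOA were also near 0.

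A second pattern is the lower expression of HIF targets. HIF is degraded after hydroxylation by enzymes that use iron and for which ascorbate can serve as a reductant, so a candidate explanation is that AA2P lowered HIF activity. The prediction of a lower median was written before the data were examined for it, and the median was -0.797. VEGFA was not lower, the estimated correlation gave an adjusted p of 0.154, and HIF protein was not measured, so other causes of lower glycolytic and collagen processing transcripts stay open.

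The groups were also compared with other splits of the 6 libraries: 1 of the 10 splits, the real one, gave 6615 called genes, and the highest of the others gave 0. With 10 splits the share cannot fall below 0.1, so the splits are too few to decide.

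The last pattern is AA2P library 3, which lay nearer the controls and, with 23122000 counts, was deeper than the other AA2P libraries. With all 6 libraries thinned to 18747307 counts (10 draws), its mean correlation to the controls was 0.970 against 0.961 for library 2, a gap of 0.00883 where full depth gave 0.00919, which argues against depth. If control RNA or cells had been mixed in, genes that rose and genes that fell would need the same control share. The median shares were 26.3% (interquartile range 17.2% to 35.0%) for genes that rose and 11.7% (6.34% to 19.1%) for genes that fell. Taken as fell minus rose, the difference was -14.6 points. By the rule set beforehand, that only ranges without overlap count against mixing, this was first read as favouring it, and a condition added after these values were seen, that each median lie inside the other range, moved the reading to undecided. The test therefore leaves mixing undecided. Some genes had not moved toward the controls: P4HA1 was at 93.5 CPM in library 3, 100 and 93.6 CPM in libraries 1 and 2 and 366 CPM in controls. LDHA was at 641, 687 and 643 CPM in the same order, against 2008 CPM in controls. Mixing would have raised both unless their own level in library 3 was lower, and both were named for small p-values. A weaker response of this culture was not tested.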
